A study of Homo sapiens with 6 samples.

How the data were processed

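RNA was measured in MCF7 cells, an established line of human breast carcinoma cells, after transfection with plasmids that carry a short hairpin RNA (shRNA). Per the labels, 3 samples received an shRNA against the long non-coding RNA FAM83H-AS1 and 3 received a control shRNA directed to GFP, a protein with no human gene. Total RNA was extracted with Trizol and labelled with biotin for a whole-transcript array, per the labels' protocols. Each sample was hybridised to its own Affymetrix Human Transcriptome Array, which summarises many short probes into a value per transcript cluster, called a feature here. Whether the 3 samples of a group came from separate cultures is not given in the sources used here, so p-values measure the spread between these samples, which may be technical.

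The deposited values were log2 expression values made with SST-RMA, per the labels. SST-RMA changes the scale of the probe signals and then corrects background, normalizes by quantiles and summarises per feature. The submitters' processing notes name Affymetrix Expression Console and RMA, while the series' design text names another Affymetrix program for exon arrays. Settings, software versions and the genome build were not given in the sources used here. The log2 scale was checked on the values, which ran from 1.35 to 19.9 over the 6 arrays. Array medians over the tested features still differed, from 5.07 to 5.16. Quantile normalization tends to pull arrays together, so a shift shared by most transcripts could be partly removed before deposit. An array gives no read depth, and the number of arrays limits the precision.

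The table held 70523 features. The 2995 array control features were left out, and 67528 features were tested. Names came from the platform annotation in use at GEO, with 23781 features that have 1 gene symbol, 1543 with several and 42204 with none listed. No gene was named from a feature with several symbols, and a feature without a listed symbol is unnamed here. The symbols were compared with a RefSeq gene table of the assembly GRCh38.p14 through their gene identifiers. Where an identifier had a match, 0 symbols needed an update. Symbols without a match, FAM83H-AS1 among them, were kept as the platform annotation gives them. That table served for names and for the order of neighbouring genes, and no coordinates were printed because the build behind the array annotation was not given. Of the tested features, 2380 shared their values on all 6 arrays with another feature.

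The comparison was FAM83H-AS1 shRNA minus control shRNA on all 6 arrays. It was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, equal array weights, no covariate), two-sided, with Benjamini-Hochberg adjustment over the tested features and a threshold of 0.05. All SEs of single features are from this fit. Features at unadjusted p under 0.05 with a difference of at least 1.5-fold were counted as well. FAM83H-AS1 and the means of the gene lists also had an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3 arrays.

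A set of 51 gene lists (pathways, gene families, markers of other cell types and the neighbours of FAM83H-AS1) was fixed, like the tests, the alternatives and the rule for named genes, before the data were examined. Each gene was represented by its feature with the highest mean over the 6 arrays, which left 22465 genes. The 50 lists with at least 5 measured members were tested with camera in limma at its preset correlation of 0.01 between genes. Their p-values were adjusted over the lists. Camera with an estimated correlation and fry stand beside it. The median of each list was also placed among the medians of 10000 random lists matched on mean expression in 50 bins.

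Named genes were FAM83H-AS1 and FAM83H, then 12 genes per direction. These had exactly 1 symbol, a higher group mean above the median of the tested features, and 2 groups of values that did not overlap. Symbols of small RNA families and uncharacterised loci were left out. Genes at adjusted p under 0.05 came first, ranked by difference, and the places left were filled with the largest differences at unadjusted p under 0.01, given as values that did not pass. In each list described, up to 4 members with the smallest unadjusted p could be named, as could every neighbour of FAM83H-AS1.

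The steps were tested on simulated arrays drawn from the real means and spreads of the 67528 features, with 200 features changed, in 10 simulations per size. For FAM83H-AS1 shRNA against control shRNA, 83.1% of features changed by 2-fold and 98.8% of features changed by 4-fold were recovered at adjusted p under 0.05. A mean of 8.8 and 10.1 unchanged features were called in those simulations, and 0.2 where no feature was changed. These rates hold for 200 changed features with independent noise. With fewer changed features the adjustment is stricter, so they do not show that a 2-fold change would be called in the real data. There IFI6, at 2.14-fold, and IFI27, at 2.08-fold, had a limma adjusted p of 0.969. A list of 46 among 22465 genes, shifted by −0.2 with independent genes, was called at unadjusted camera p under 0.05 in 100% of 100 simulations with the preset and the estimated correlation. The real interferon list had an estimated correlation of 0.102, and its p-value was adjusted over the lists. The simulation therefore does not show how the test behaves for genes that move together.

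The alternatives were another round of quantile normalization, equal array medians, the replicate number as a block, array weights, leaving out each array, other variance settings, other thresholds and other sets of features. For the lists they also covered the estimated correlation, fry, ranks and the mean of all features of a gene. Cyclic loess, counting identical features once, the interferon list without IFI6 and IFI27 and a second interferon list were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.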

Results

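The expression of coding and non-coding transcripts was compared between MCF7 cells that had received an shRNA against FAM83H-AS1 and MCF7 cells that had received a control shRNA. MCF7 is a luminal, oestrogen receptor-positive line of breast carcinoma cells. FAM83H-AS1 is a transcript named for its place antisense to FAM83H on chromosome 8. Each group held 3 samples with an array each, and 67528 features were tested. Correlations between arrays over all features ranged from 0.991 to 0.995.

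The signal of FAM83H-AS1 itself did not separate the groups. Its feature (TC08000833.hg.1) had a log2 value of 8.53 ± 0.12 (SD, n = 3) on the control shRNA arrays and 8.42 ± 0.06 (SD, n = 3) on the FAM83H-AS1 shRNA arrays. The single values were 8.43, 8.66 and 8.49 on the control arrays against 8.38, 8.40 and 8.49. The difference was −0.11 with a 95% confidence interval of −0.33 to 0.12 in limma, with an adjusted p of 0.981. This corresponds to 93.0% of the control level, with an interval of 79.5% to 108.7%. The exact two-sided permutation p was 0.2, where the smallest possible was 0.1. The feature lay at least 0.72 above the highest of the 23 background control features on every array. FAM83H, the neighbouring gene, is needed for enamel formation and differed by 0.01 ± 0.10 (SE, adjusted p in limma 0.999), a value that turned negative with quantile normalization applied again and with cyclic loess. The RefSeq table holds FAM83H-AS1 as an older name of IQANK1, a protein-coding gene between MIR4664 and SCRIB on chromosome 8. The arrays are named by their labels throughout, since the target gave no check of them.

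Interferon-stimulated genes, which cells switch on in response to interferons and viral RNA, were lower as a list on the FAM83H-AS1 shRNA arrays with the preset correlation of camera (adjusted p 9.51e-21). The call did not hold with an estimated correlation of 0.102, where the adjusted p was 0.381 (unadjusted 0.00762), or with fry, where it was 0.12 (unadjusted 0.0024). Of the 46 members measured, 44 had a lower mean and 2 a higher mean, with a median log2 difference of −0.20. STAT1, STAT2, IRF9 and TRIM22 were in the fixed list but not measured. The size of the difference varied among members. Named after their values were seen, the 2 higher members were USP18 (0.08) and IFIT3 (0.0065), and MX1 and IFIT2 differed by −0.10 and −0.05. IFI6 and IFI27, small interferon-induced membrane proteins, had the largest differences. IFI6 went from 15.4 ± 0.10 to 14.3 ± 0.28 (SD, n = 3 per group), a 2.14-fold lower level. IFI27 went from 12.5 ± 0.08 to 11.4 ± 0.23 (SD, n = 3 per group), a 2.08-fold lower level. IFIT1, which binds the ends of viral RNA, differed by −0.68 ± 0.14 (SE) from a control mean of 5.85, and PARP9, an ADP-ribosyltransferase family member, by −0.42 ± 0.09 (SE). Adjusted over the list alone, 9 members were lower at p under 0.05 and 0 were higher. The 5 others of these, named after their values were seen, were DDX60, OAS1, EIF2AK2 and the RNA sensors RIGI and IFIH1, with differences of −0.45, −0.43, −0.31, −0.31 and −0.30. Adjusted over all features, 0 members passed in limma, and 17 were lower at unadjusted p under 0.05.

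**Figure D1:**
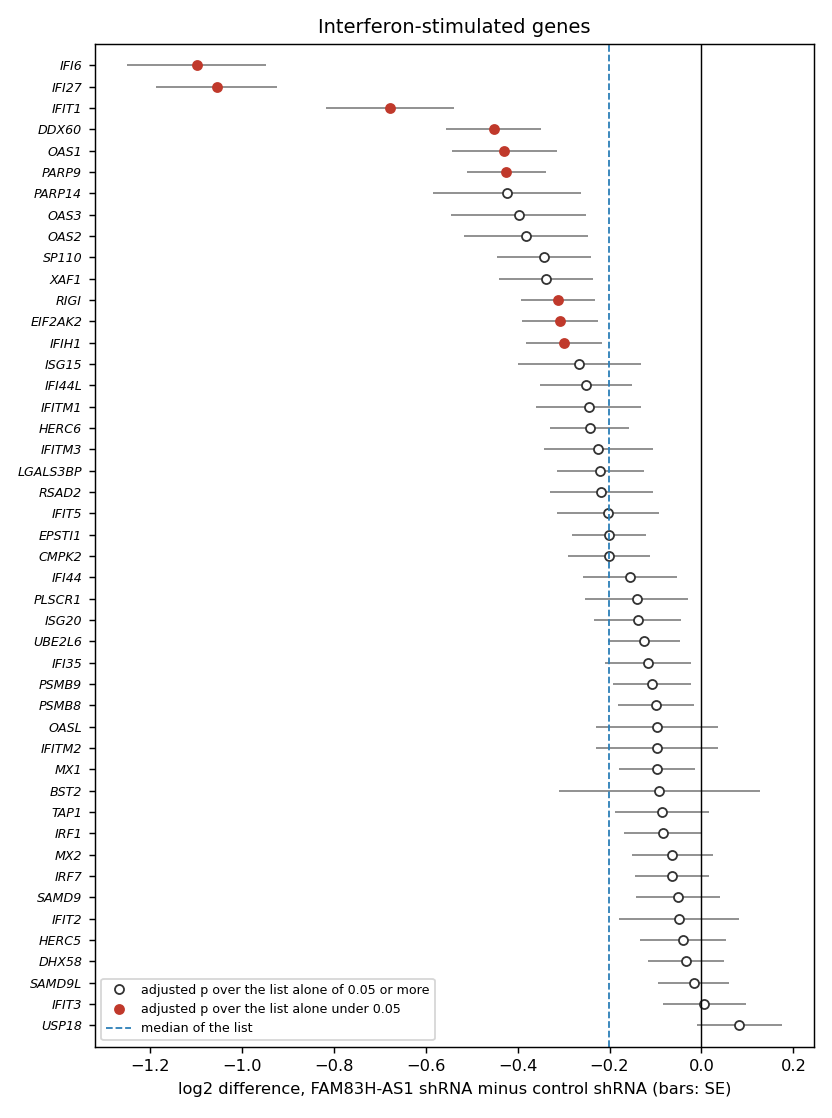
Log2 differences (FAM83H-AS1 shRNA minus control shRNA, bars show the SE) of the 46 measured interferon-stimulated genes, sorted by size. Filled points mark the 9 members at adjusted p under 0.05 over the list alone, and 44 of the points lie below 0 around a median of −0.20.

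The mean deviation of the interferon list was 0.12 ± 0.05 on the control arrays and −0.12 ± 0.03 on the FAM83H-AS1 shRNA arrays (SD, n = 3 per group), and every control array lay above every FAM83H-AS1 shRNA array. The exact permutation p of these means was 0.1, the smallest possible, as it was for 4 of the 50 tested lists in all (the others were apical junction, fibroblast markers and the ERBB family), where chance gives 5. Of 10000 random lists matched on expression, 0 had a median as low, but such lists ignore the correlation between genes, and 11 of the 50 tested lists, the olfactory receptors among them, lay outside the central 95% of theirs.

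Over all features, limma found 0 higher and 0 lower at adjusted p under 0.05, with a smallest adjusted p of 0.969. At unadjusted p under 0.05 there were 1160 higher and 2280 lower features, 3440 in all, where chance alone gives 3376. With array medians made equal these became 1895 and 1578, so that the share of higher features moved from 33.7% to 54.6%. Quantile normalization applied again gave 47.2%, and cyclic loess 47.9%. The groups of values did not overlap for 7111 features or 10.5%, where chance gives 10%. A difference of at least 1.5-fold at unadjusted p under 0.05 was met by 91 higher and 189 lower features, or 118 and 129 with equal array medians. The higher count was 348 without control array 2, 187 without FAM83H-AS1 shRNA array 1 and 185 without array 3 of that group. The lower count was 315 without control array 1, 321 without FAM83H-AS1 shRNA array 1 and 305 without array 2 of that group. Only 22 of these 280 features had 1 gene symbol, 5 of them higher. Named after their values were seen, the 5 were the microRNA genes MIR548W and MIR4536-1, the Y RNA pseudogene RNY4P9, CASP14 and LINC00052.

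None of the other named genes passed the adjustment (limma adjusted p 0.969 for each). CLDN1, a claudin of tight junctions, was 0.52 ± 0.13 (SE) above the control shRNA arrays. ITGA2, a collagen-binding integrin subunit, was 0.42 ± 0.09 above them, and TNFRSF21, a death-domain receptor, 0.40 ± 0.08. The long non-coding RNA LINC00052 had the largest positive difference among the 12 genes that the rule named in this direction, 0.62 ± 0.14, from a control mean of 12.04. The keratin KRT23 differed by 0.41 ± 0.12, the glycine receptor subunit GLRA3 by 0.41 ± 0.09, the lipase family member LIPK by 0.42 ± 0.12 (control mean 5.35) and CCDC83 by 0.43 ± 0.10. H3-5, a histone H3 gene, differed by 0.58 ± 0.16. RPL13AP3 and TMSB4XP4, pseudogenes whose probes may also bind transcripts of their parent genes, differed by 0.54 ± 0.15 (control mean 5.46) and 0.49 ± 0.14, and the immunoglobulin segment IGLJ7 by 0.57 ± 0.14.

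On the negative side, CXCL12, an oestrogen-induced chemokine, differed by −0.54 ± 0.14 (SE). DRAM1, a p53-induced regulator of autophagy, differed by −0.51 ± 0.13, and the glutathione transferase GSTM3 by −0.46 ± 0.11. The immunoglobulin segment IGHD3-16 differed by −0.66 ± 0.17. IL20RB-AS1, at low means of 5.34 and 4.59, differed by −0.76 ± 0.13. The others had low signals too, with means between 4.81 for ACTL7A on the FAM83H-AS1 shRNA arrays and 5.73 for OR1L3 on the control arrays. ACTL7A, an actin-like gene of the testis, differed by −0.53 ± 0.14, the olfactory receptor OR1L3 by −0.52 ± 0.11, IFITM5 by −0.49 ± 0.09 and the secretoglobin SCGB1D4 by −0.47 ± 0.10. IFITM5 is a bone-specific relative of the interferon-induced IFITM genes.

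**Figure D2:**
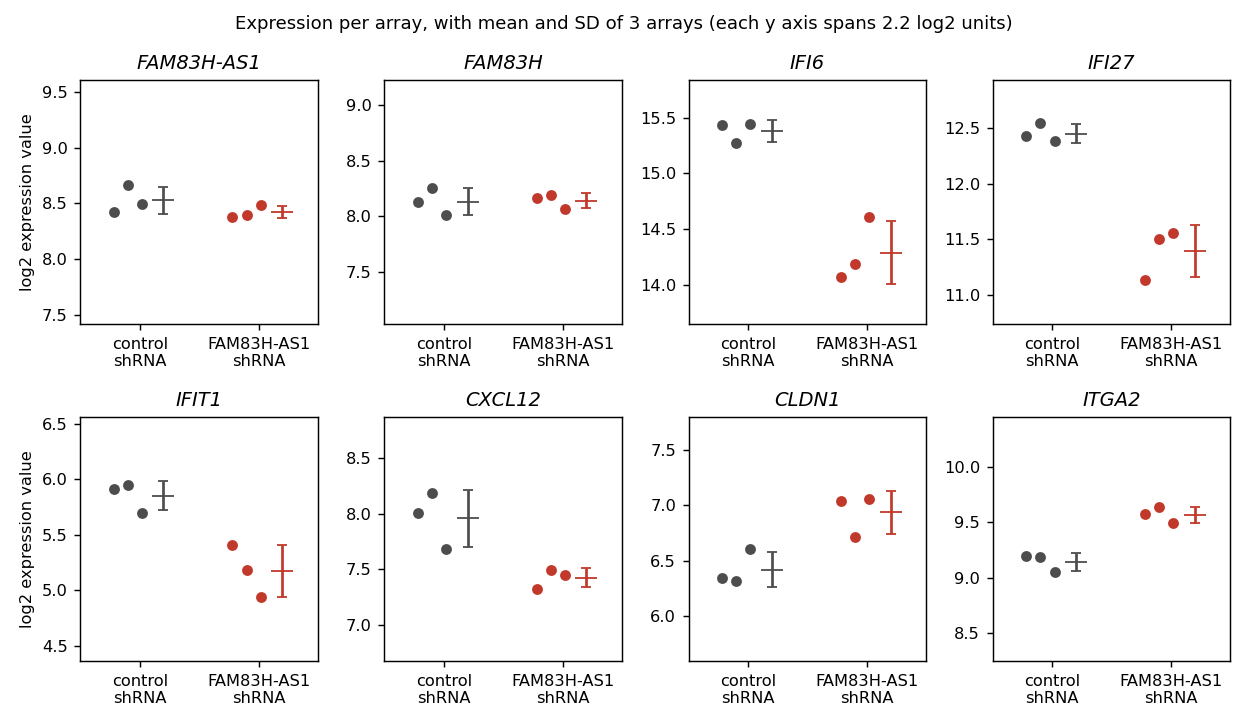
Log2 expression values per array (points) of FAM83H-AS1, FAM83H and 6 further named genes, with the mean and SD of 3 arrays beside them for each group. The groups overlap for FAM83H-AS1 and FAM83H. They lie apart for the others, as for IFI6 with means of 15.4 and 14.3, which was a condition for naming those genes.

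Besides the interferon list, 13 of the 50 lists tested were called with the preset correlation, 12 of them higher and the olfactory receptors lower. None of these calls held with an estimated correlation, where the adjusted p of each list was 0.769 or 0.882, or with fry, where the adjusted p was 0.918. In each of the 13 lists, 0 members passed in limma when adjusted over the list alone or over all features. Replication-dependent histones, which package newly made DNA, had a median difference of 0.32 over 19 members, or 0.14, still called, with array weights. H2BC3 differed by 0.57 ± 0.23 (SE) and H2BC11 by 0.50 ± 0.23. DNA replication and G1/S genes had a median of 0.14 over 42 members, 40 of them with a higher mean, and the cyclin gene CCNE2 differed by 0.36 ± 0.15. Mitosis and G2/M genes had a median of 0.076 over 50 members, and CDK1, the kinase that drives entry into mitosis, differed by 0.35 ± 0.17. The cyclins, CDKs and CDK inhibitors had a median of 0.071, DNA damage repair genes 0.087 with BRCA1 at 0.24 ± 0.12, and MYC targets and ribosome biogenesis 0.088.

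These lists differed as much between arrays of a group as between the groups. The estimated correlation between members was 0.679 for the histones, 0.905 for DNA replication and 0.893 for mitosis. The exact permutation p of the list means, which takes no account of the replicate numbers, was 0.4, 0.6 and 0.6. For DNA replication and mitosis, part of the spread followed these numbers. The DNA replication list deviated by 0.19, −0.03 and −0.37 on control arrays 1 to 3. On FAM83H-AS1 shRNA arrays 1 to 3 it deviated by 0.31, 0.08 and −0.18. It was thus higher at each number, as was mitosis, while the histones were lower at number 2. That equal numbers mark pairs stayed a hint from the data. The calls with an array left out or another scaling used the preset 0.01, which takes the members as far more independent. The mitosis list deviated by −0.42 on control array 3 and −0.25 on FAM83H-AS1 shRNA array 3, against 0.13 to 0.24 on the 4 other arrays. The histone list deviated by 0.56 on FAM83H-AS1 shRNA array 1 and −0.46 on control array 3. The histones kept their call without each single array, with a median of 0.16 without control array 3 and 0.11 without FAM83H-AS1 shRNA array 1. Without control array 3 the median became −0.020 for DNA replication, 0.043 for DNA damage repair, 0.064 for the cyclins and −0.0056 for MYC targets, each no longer called, and −0.090 for mitosis, called lower. That setting kept the low FAM83H-AS1 shRNA array 3 and set it against control arrays that were not low for mitosis. Without FAM83H-AS1 shRNA array 1 the median was 0.0045 for DNA replication, 0.0004 for mitosis, −0.014 for MYC targets and 0.041 for the cyclins, none of them called. The cyclin list also lost its call without control array 2 (0.087) and FAM83H-AS1 shRNA array 2 (0.096), MYC targets without the first of these (0.088) and mitosis without the second (0.032). Still called were DNA replication, mitosis and MYC targets without control array 1 (0.26, 0.18 and 0.15) and without FAM83H-AS1 shRNA array 3 (0.28, 0.23 and 0.17), DNA damage repair without control array 1 (0.13) and mitosis without control array 2 (0.17).

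Other settings ended several of these calls. With quantile normalization applied again the median was 0.033 for DNA damage repair (adjusted p 0.261), 0.017 for mitosis (0.493), 0.015 for the cyclins (0.493) and 0.018 for MYC targets (0.782). With cyclic loess it was 0.046 (adjusted p 0.161), 0.022 (0.487), 0.038 (0.42) and 0.034 (0.689). DNA replication stayed called at 0.075 and 0.088 with these 2 scalings. With array medians made equal, mitosis (0.11), the cyclins (0.11) and MYC targets (0.12) were not called, each at an adjusted p of 0.0591, nor were they with features above the median level (0.237, 0.163 and 0.237). Array weights ended the calls of MYC targets (0.063) and the cyclins (0.055) and gave 0.13, still called, for mitosis. The weight was 3.35 for FAM83H-AS1 shRNA array 2, against 0.562 and 0.627 for arrays 1 and 3 of that group. Control arrays had 0.891 to 1.04, so this setting rests mostly on 1 array of the FAM83H-AS1 shRNA group.

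**Figure D3:**
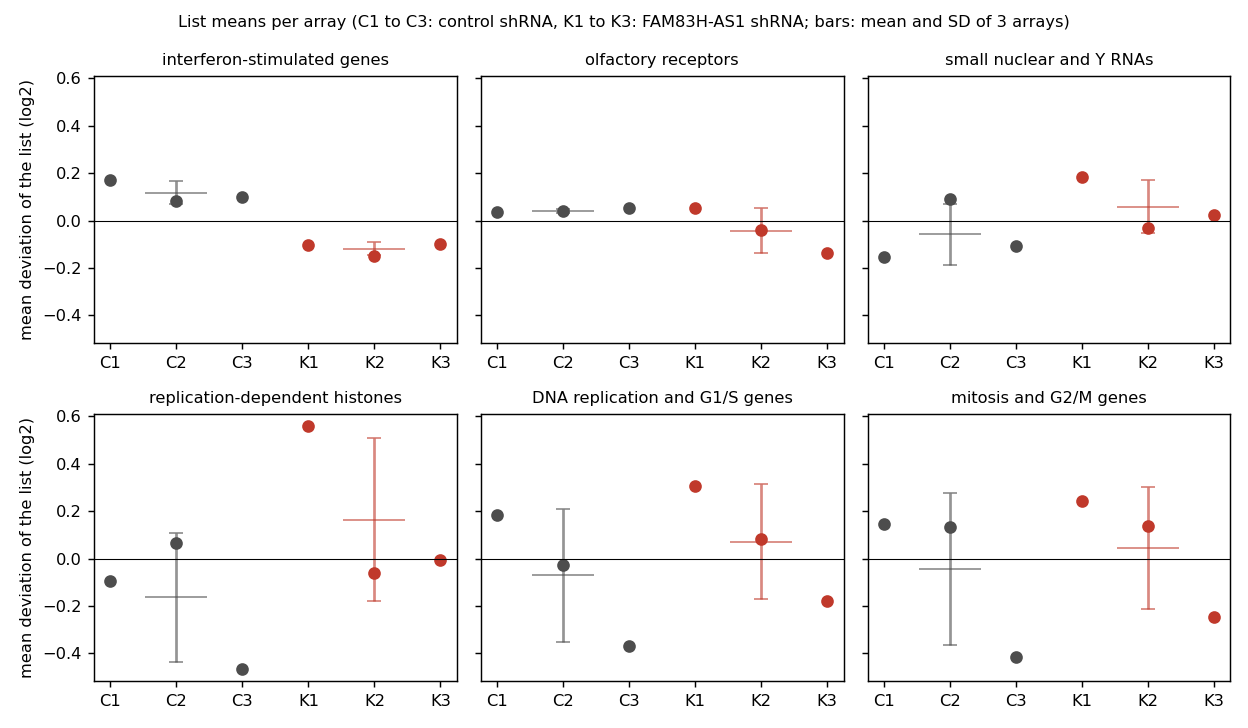
Mean log2 deviation of 6 called gene lists on each array (points) from the mean over the 6 arrays, with the mean and SD of 3 arrays per group as bars. The interferon list separates the groups, at 0.08 to 0.17 against −0.15 to −0.10, whereas the lists of replication and mitosis are low on array 3 of both groups.

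The immediate-early and MAPK feedback genes had a median of 0.12 over 26 members, with the phosphatase gene DUSP6 at 0.28 ± 0.12 (SE). The list lost its call without control array 2 (0.076), without FAM83H-AS1 shRNA array 1 (0.050) and with array weights (0.041). Small nuclear and Y RNAs had a median of 0.11 over 284 members and kept the call without each single array, but at 0.060 without control array 1, 0.20 without control array 2 and 0.047 without FAM83H-AS1 shRNA array 1, and at 0.056 with array weights. KRAB zinc finger genes had 0.041 over 502 members and −0.0001, not called, without FAM83H-AS1 shRNA array 3. This list lost its call with quantile normalization applied again (0.016, adjusted p 0.157) and with cyclic loess (0.025), and kept it at 0.024 without control array 1, 0.071 without FAM83H-AS1 shRNA array 1 and 0.076 with array medians made equal. Cytosolic ribosomal proteins had a median of 0.056, which became −0.0078 with quantile normalization applied again, and was 0.033, not called, without FAM83H-AS1 shRNA array 1. Cyclic loess (0.0049) and array weights (0.030) ended the call of these ribosomal proteins too, and it held at 0.10 without control array 2, 0.11 without FAM83H-AS1 shRNA array 2 and 0.091 with array medians made equal. Apical junction and desmosome genes had 0.056, which became −0.0073 with quantile normalization applied again and 0.0016 with cyclic loess, neither called, was 0.091 with array medians made equal, and was 0.023, not called, without FAM83H-AS1 shRNA array 3. Its members CLDN1 and DSC2, a desmosomal cadherin, differed by 0.52 and 0.37. Spliceosome and SR proteins had 0.058, which became −0.0070 with that normalization and −0.0045 with cyclic loess, neither called, and lost the call without control array 3 (0.029) and without FAM83H-AS1 shRNA array 3 (0.050). It was 0.091, still called, without FAM83H-AS1 shRNA array 1 and 0.093 with array medians made equal, and lost the call with features above the median level (adjusted p 0.109). The 394 olfactory receptors, the odorant receptors of the nose, had a median of −0.079, and −0.042 with no call without FAM83H-AS1 shRNA array 3. They were not called with quantile normalization applied again or cyclic loess, at −0.037 with each, and stayed called at −0.044 with array medians made equal and −0.13 with features above the median level. Of the 14 called lists, 6 had medians within the central 95% of random lists matched on expression. The middle median of those random lists was 0.053 for ribosomal proteins, 0.054 for the spliceosome and 0.045 for apical junction. For mitosis it was 0.0505, for MYC targets 0.046 and for the cyclins 0.0365. With the deposited values, genes of such levels were thus higher in general, and these 6 medians do not set the lists apart from them.

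The lists closest to the identity of MCF7 cells were not called. The oestrogen-induced genes had a median of 0.035 over 37 members (camera adjusted p 0.175), which became −0.019 with quantile normalization applied again. The luminal identity genes had 0.031 over 23 members (adjusted p 0.343), negative with quantile normalization applied again and with cyclic loess. Its members ESRP1, an epithelial splicing factor, and ESR1, the oestrogen receptor, differed by 0.31 ± 0.08 and −0.20 ± 0.11 (SE). Mesenchymal genes had a median of 0.0028 (adjusted p 0.928) and basal markers 0.014 (adjusted p 0.248). The p53 targets had −0.0003 (adjusted p 0.671), pro-apoptotic genes −0.0061 (adjusted p 0.928) and anti-apoptotic genes 0.054 (adjusted p 0.661, negative with quantile normalization applied again and with cyclic loess). NF-kB and inflammatory genes had −0.010 (adjusted p 0.632, positive under the other scalings), with the chemokine gene CXCL8 at −0.25 ± 0.08. Markers of fibroblasts (−0.062, adjusted p 0.0598), endothelium (−0.042, adjusted p 0.0988), leukocytes (−0.044, adjusted p 0.109, positive with quantile normalization applied again and with cyclic loess) and adipocytes (−0.069, adjusted p 0.343) were not called either. Random lists matched on expression had middle medians of −0.045, −0.036, −0.0405 and −0.039 for these markers, in that order. With the deposited values, genes of such low levels were thus lower in general. The endothelial median was −0.0074 with array medians made equal and −0.002 with cyclic loess, and the fibroblast median −0.027 and −0.021. Quantile normalization applied again or cyclic loess turned the sign of the median for 18 of the 36 lists not called. For 7 of them the median, the mean and the camera direction differed in sign, namely fatty acid synthesis, RNA interference, Hippo YAP targets, pro-apoptotic genes, ERBB family, Wnt targets and Notch genes.

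The neighbours of FAM83H-AS1 at 8q24.3 had a median difference of 0.030 over 27 measured genes (camera adjusted p 0.361). The zinc finger gene ZNF623 differed by 0.38 ± 0.13 (SE), PARP10 by −0.19 ± 0.08, PUF60 by 0.03 ± 0.13 and MAPK15 by −0.03 ± 0.08. Of these, 0 passed at adjusted p under 0.05 over the list alone, and 1 was higher and 1 lower at unadjusted p under 0.05. The 8 measured members of the FAM83 family had a median of −0.045 (camera adjusted p 0.717).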

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

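FAM83H-AS1 stayed negative and did not pass the threshold under any alternative tried, from −0.16 to −0.038. The interferon list stayed lower under each, from −0.16 to −0.23 when an array was left out, but at an unchanged median of −0.20 it missed the threshold with an estimated correlation (adjusted p 0.381) and with fry (0.12). The counts at adjusted p under 0.05 stayed at 0 with the alternatives in which they were computed. The 24 other named genes never passed and never changed sign. They were named for groups of values that did not overlap, so leaving out an array or other variance settings could not turn their sign. FAM83H, at a difference near 0, turned to −0.036 with quantile normalization applied again and −0.031 with cyclic loess, and ranged from −0.048 to 0.074 without an array. The numbers of lists called higher and lower became 4 and 1 with quantile normalization applied again and 4 and 1 with cyclic loess, 0 and 0 with an estimated correlation and 0 and 0 with fry. The lower lists became 4 with features above the median level. Without an array there were 8 to 18 higher and 1 to 4 lower lists. The 1.5-fold counts became 34 higher and 99 lower with no moderation of the variance, and 57 and 79 with features above the median level. They became 5 and 17 with features that have 1 gene symbol, and 8 and 12 with a minimum of 2-fold. The last 3 of these 4 settings remove features or raise the threshold by construction. Array weights gave 165 higher, and leaving out an array gave 97 to 348 higher and 189 to 321 lower. Cytosolic ribosomal proteins turned to −0.0078 with quantile normalization applied again. Without an array the mitosis list ranged from −0.090 to 0.23 and MYC targets from −0.014 to 0.17. The cause was not tested for the other changes.

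The labels give both groups the replicate numbers 1 to 3. Deviations from the group means correlated at 0.219, −0.013 and 0.269 within the pairs of equal number, and 4 of the 6 samples correlated best with their own number, so the pairing stayed a hint from the data. With the replicate number as a block, 106 features were at least 1.5-fold higher and 196 lower, 14 lists were called higher and 2 lower, and the 0 features at adjusted p under 0.05 stayed at 0. The background control probes had medians of 3.41 to 3.49 on the arrays, against 5.07 to 5.16 over the tested features. What signal over background limits here was not tested.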

Other observations

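The tests of single arrays, of IFI6 and IFI27, of the plasmids, of the level of FAM83H-AS1 and of other splits of the arrays were chosen after the results were seen, as were all lists in the next paragraph and cyclic loess as a setting.

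A second list of interferon-induced genes, with no member in common with the first, had a median log2 difference of −0.073 over 47 genes, 36 of them with a lower mean (camera p 4.1e-05, or p 0.00773 with an estimated correlation, in limma). Among its members, SLFN5 differed by −0.45 ± 0.14 (SE), DTX3L, the partner of PARP9, by −0.34 ± 0.11, SP100 by −0.30 ± 0.11 and PARP12 by −0.25 ± 0.09. Genes of MHC class I antigen presentation had a median of −0.037 over 14 genes (camera p 0.542), and interferon ligands and receptors −0.016 over 17 genes (camera p 0.441). Genes of double-stranded RNA and DNA sensing outside the first list, not all of them sensors, had 0.029 over 11 genes (camera p 0.991), with TLR3 at −0.28 ± 0.09.

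Apart from the groups, the arrays differed in several gene groups at once. The oestrogen-induced list deviated by −0.31 on control array 3 and −0.16 on FAM83H-AS1 shRNA array 3, against 0.20 and 0.23 on array 1 of the groups. NRF2 targets deviated by −0.25 and −0.23 on the arrays numbered 3, against 0.24 and 0.22 on those numbered 1. The poly-A control dap, added to the RNA before labelling, read 10.6 on control array 2 and FAM83H-AS1 shRNA array 1 and 9.54 to 9.84 on the 4 others. Of the 2995 array control features, 0 differed between the groups at adjusted p under 0.05 in limma (smallest adjusted p 0.245).

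The lower interferon-stimulated genes are the pattern that stands out most between the groups. The values argue against differences between arrays that follow the level, since the median stayed at −0.17 after cyclic loess, and against a single array, since the highest median without any array was −0.16. The 44 members other than IFI6 and IFI27 had a median of −0.18, so those 2 genes are not the whole of it. Leaving out 2 members can move a median only slightly, so this value adds little to the −0.20 of the full list. The choice of members stays open: the second list had −0.073 with 0 of 10000 matched random lists as low, which met the bound set for this test, but 11 of the 50 fixed lists also lay outside the central 95% of theirs, and the MHC class I list had only 63 of 10000 as low at a camera p of 0.542. Depletion of FAM83H-AS1 cannot be told apart from another difference between the plasmids, such as a different response to the hairpin or to the transfected DNA, because there was 1 targeting and 1 control shRNA and FAM83H-AS1 differed by −0.11 within its spread.

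FAM83H-AS1 was not measurably lower on the FAM83H-AS1 shRNA arrays. A signal at background level is argued against, since the feature lay above the highest of the 23 background control features on each array, by at least 0.72, where the largest SD of any of these features over the arrays was 0.52. This does not address binding of other transcripts. Probes that read transcripts the hairpin does not target, a partial depletion inside the interval of the difference and a late time of harvest stay open and were not tested.

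The olfactory receptors were called lower with the preset correlation, but not with an estimated correlation (adjusted p 0.882) or with fry (adjusted p 0.918), at a median of −0.079 ± 0.011 (SE of the median over members). After cyclic loess the median was −0.037 ± 0.011 and the camera call ended (adjusted p 0.0901), for which the cause was not tested. Without FAM83H-AS1 shRNA array 3 it was −0.042 and not called. The first value lies on the side of the bound of −0.04 that differences following the level predict, and the second on the other side. Both lie within the SE of it, a margin added after the values were seen. Random lists matched on expression had a middle median of −0.047 with the deposited values, so part of the difference was shared with genes of that level. Of those 10000 lists, 0 were as low as the olfactory receptors, but they ignore the correlation between genes. The list deviated by 0.035, 0.040 and 0.052 on control arrays 1 to 3 and by 0.052, −0.041 and −0.14 on FAM83H-AS1 shRNA arrays 1 to 3. FAM83H-AS1 shRNA array 1 was thus not lower than the control arrays, and the exact permutation p of the list means was 0.3. Whether differences between arrays that follow the level, or a single array, are the source of the whole difference stays open for this list.

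With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. For the interferon list at the preset correlation, 1 of the 10 splits, the real arrangement, gave a camera −log10 p of 21.7, and the highest other gave 5.76. With an estimated correlation the camera p of the real arrangement was 0.00762 (adjusted 0.381), and each of the 10 splits gave 0 called lists. For features at adjusted p under 0.05, all 10 of 10 gave 0, the highest other included. For features at unadjusted p under 0.05 and 1.5-fold, 6 of 10 gave at least the real 280, and the highest other gave 679. That split set control arrays 1 and 2 with FAM83H-AS1 shRNA array 1 against the rest. For lists called with the preset correlation, 6 of 10 gave at least the real 14, and the highest other gave 20.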
